A study of Mus musculus with 15 samples.

How the data were processed

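Gene expression was measured by RNA sequencing in 15 libraries from C57BL/6 mouse embryonic fibroblasts, 3 in each of 5 groups. Per the labels, libraries were made from 100 to 200 ng of total RNA with the TruSeq RNA v2 kit, which does not mark the strand of origin. The deposited table holds raw counts per gene symbol, as whole numbers, for 24062 symbols and all 15 libraries. Per the submitters' processing notes, the tools behind these counts were TopHat2 2.0.14, Bowtie2 2.2.6 and featureCounts 1.4.6 of the Subread package, with the mm10 build. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Without strand, reads of overlapping genes on opposite strands, such as Ube2c and Tnnc2, cannot be told apart. Genes with near-identical copies (histones, ribosomal proteins, serpins) are uncertain because the treatment of reads that map to several places is not given.

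Each column of the table was matched to a sample by its title, and each sample to its group and replicate number by the same label. The table had 0 blank symbols and 0 unused columns, and 4134 symbols had no count in any library. Total counts ran from 27059895 to 61994550 per library, and the shRb libraries were the deepest. A count of 3, the floor used here, stood for 0.0484 to 0.111 CPM in a library. Floors and counts cover counting error only. No pair of replicates agreed within sampling noise: chi-square per degree of freedom was 6.32 or more in each pair, over genes with a mean count of at least 20. The first 3 principal components of log2 CPM held 41.0%, 12.0% and 10.4% of the variance. Symbols were matched to GENCODE M21, an annotation of GRCm38, for coordinates and overlaps: 22750 (94.5%) matched. Of 366 genes that could be named, 362 had 1 match and 110 had exons overlapping those of another gene.

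Group effects were tested with edgeR 4.0.16 in R 4.3.3, with quasi-likelihood fits (glmQLFit and glmQLFTest), TMM scaling and the filterByExpr filter, which left 14771 genes. All 15 libraries entered 1 fit with a term per group and no other term, so that all groups shared 1 estimate of the spread. P-values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 was a call. The comparisons were day 2 against day 0, shScr against day 0 and against day 2, shp21 and shRb against shScr, and shp21 against shRb. With 6 libraries in 2 groups of 3, no rearrangement of labels can give a share under 0.1.

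The gene lists for growth and division were p53 targets, DNA replication and E2F targets, G2/M and mitosis, replication-dependent histones, ribosomal proteins and immediate early genes. Those for secretion and matrix were inflammatory cytokines and chemokines, secreted proteases and their inhibitors, growth factors and IGF-binding proteins, extracellular matrix, complement, and contractile and myofibroblast genes. Others were interferon-stimulated genes, antigen presentation and natural killer ligands, lysosome, cholesterol biosynthesis, and markers of macrophages and blood cells, endothelium, epithelium, skeletal muscle and neurons. Each was tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 21 lists of a comparison. Where the preset call was lost with a correlation estimated from the data, that value is printed with it. The correlation was estimated without a term for the replicate number, so effects shared by replicate number could enter it. No estimate with such a term was made. Members were counted by their edgeR call over all genes tested and again with p adjusted over the list alone. Genes called at day 2 were also tested as sets in the knockdowns, with adjustment over the 2 sets of a comparison. The day-4 libraries entered the choice of these genes only through the filter, the scaling and the shared estimate of the spread.

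Genes could be named if they were a hairpin target or in a short panel (Trp53, Mdm2, Cdkn2a, Lmnb1, Mki67, Cxcl14 and Il6). Others were among the 10 largest rises or falls of a comparison with a mean of at least 5 CPM and no overlap between the groups of 3 (which chance gives for 10% of genes), leaving out predicted genes and pseudogenes. The rest were among the 4 members of a list with the smallest p in a comparison. Results for some genes that met the rule are not reported here. The design, the lists, this rule and most alternatives were chosen before the data were examined.

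The test was tried on simulated data for all 15 libraries, made from the mean levels of the shScr group. Genes were changed in the simulated shp21 libraries and tested against simulated shScr, over 14415 genes. It called 73 of 99 genes changed 1.5-fold (73.7%) and 81 of 96 changed 2-fold (84.4%), and 8 of 162 calls were false (4.94%). Camera, at its preset correlation, gave p = 5.49e-83 for a list that was changed and p = 0.508 for an unchanged list. Genes were drawn independently, so these values cannot show how camera behaves for lists whose genes vary together. Overlap between the knockdowns was set against 20 simulated draws in which nothing changed but the shScr libraries were shared.

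Groups had the same replicate numbers, so whether these pair the libraries was checked from the deviations from group means. Over the 10000 most abundant genes the 30 correlations between same-numbered libraries ran from 0.151 to 0.767 and those between different numbers from -0.539 to 0.354. Over all 14771 genes they ran from 0.0325 to 0.442, with 7 of 30 not above 0.1, and from -0.287 to 0.138. In each version the mean correlation of 14 of 15 libraries was highest with the libraries of their own number, and the first component of the deviations (50.8% and 25.9%) set replicate 2 apart in every group. The numbers were taken as pairing the libraries, after both versions were seen and before blocked calls were. The main fit, chosen earlier, has no term for the replicate number, so its calls and p-values leave this pairing out. Blocked values are given as an alternative. The hint comes from the data, since the labels state no shared culture or day.

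Alternatives were RLE size factors, library-size scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, a fit of the compared groups only, the replicate number as a block, each library left out in turn, an estimated correlation and the fry test. Library-size scaling, leaving out replicate 2 of every group, leaving out the ribosomal RNA gene Rn45s, counts thinned to the smallest library and list tests with each library left out were added after seeing the data. Left out were a search for hairpin off-targets, for which no hairpin sequence was used here, and outlier tests, which were not run on groups of 3.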

Results

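RNA sequencing was done on mouse embryonic fibroblasts (MEFs), connective-tissue cells grown from embryos, of the C57BL/6 strain. The 15 libraries fell into 5 groups of 3. Cells proliferating without irradiation were taken at day 0, and cells exposed to gamma-rays, which break DNA, were taken at day 2. At day 2 other irradiated cells were infected with lentivirus that delivers a short hairpin RNA, and these were taken at day 4. The sample titles call these day-4 cells irradiated and non-senescent. The hairpin had a scrambled sequence (shScr, the control), was directed against p21 (shp21) or was directed against Rb (shRb). The series concerned p21 and the factors that stressed cells secrete. Total counts ran from 29197479 to 32210856 per library at day 0 and from 27983422 to 42154068 at day 2. They ran from 27059895 to 37541073 in the shScr group, from 38452669 to 44319890 in the shp21 group and from 51502956 to 61994550 in the shRb group. Levels are given as CPM, counts scaled to library size with TMM factors, mean ± SD of 3 libraries, and fold changes as log2 ± SE. The labels do not say that replicates were separate cultures, so p-values measured only the spread between these samples, which may be technical.

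The genes aimed at by the hairpins were lower in the libraries labelled for them. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, is a protein-coding gene on chromosome 17 at 29090976 to 29100727 of the mm10 (GRCm38) build, where its exons overlap those of the predicted gene AC167363.2. Its level was 329 ± 12.1 CPM at day 0, 722 ± 16.6 at day 2, 759 ± 5.63 with shScr, 175 ± 18.6 with shp21 and 904 ± 38.9 with shRb. Against shScr, Cdkn1a fell by 2.12 ± 0.06 on the log2 scale with shp21 (adjusted p = 1.35e-11) and rose with shRb (0.25 ± 0.06, adjusted p = 0.00768). Rb1, which encodes the retinoblastoma protein that restrains E2F transcription factors, is a protein-coding gene on chromosome 14 at 73183673 to 73325822, where its exons overlap those of Lpar6 and Rcbtb2. Its level was 13.5 ± 0.125, 20.5 ± 1.16, 21.1 ± 2.29, 32.4 ± 2.46 and 4.43 ± 0.851 CPM in the same order of groups. Rb1 fell by 2.25 ± 0.12 with shRb (adjusted p = 7.83e-09) and rose with shp21 (0.62 ± 0.11, adjusted p = 0.00047). The adjusted p-values came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

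**Figure D1:**
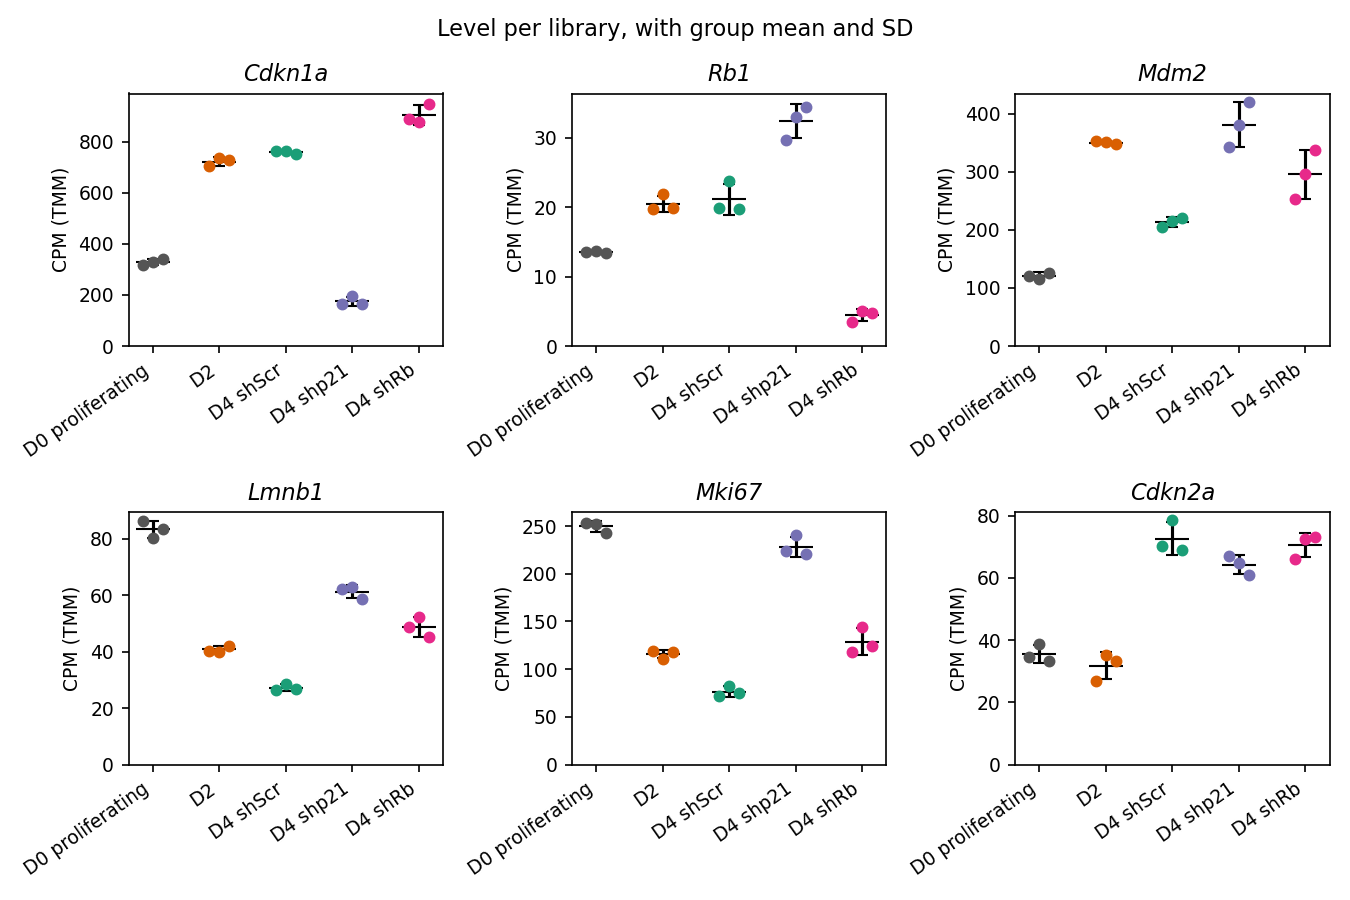
Level of Cdkn1a, Rb1, Mdm2, Lmnb1, Mki67 and Cdkn2a in CPM, 1 point per library, with the mean and SD of each group of 3. Cdkn1a averaged 175 CPM with shp21 against 759 with shScr, and Rb1 averaged 4.43 CPM with shRb against 21.1.

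Irradiated cells at day 2 were compared with proliferating cells at day 0 to ask what gamma-irradiation changed before any virus was added, although the groups also differed in days of culture. Genes that p53 activates rose, and genes of DNA replication and mitosis fell. Mdm2, which encodes the ubiquitin ligase of p53, rose from 121 ± 5.66 to 350.2 ± 2.61 CPM (1.53 ± 0.09), and Lmnb1, which encodes lamin B1 of the nuclear envelope, went from 83.4 ± 3.01 down to 40.8 ± 1.04 CPM (-1.03 ± 0.06). Icam1, an adhesion molecule that leukocytes bind, rose from 4.97 ± 0.890 to 27.5 ± 3.04 CPM, and Serpine2, a secreted protease inhibitor, from 59.1 ± 5.36 to 250.1 ± 40.3 CPM. Among the genes with the largest rises were also Perp (2.90 ± 0.37), Mcpt8 (2.48 ± 0.31), Serpinb2 (2.09 ± 0.32) and Gdf15 (2.08 ± 0.22). The largest falls included Aldh1l2 (-1.63 ± 0.17), Trib3 (-1.60 ± 0.23), Slc7a5 (-1.48 ± 0.16), an amino acid transporter, and Pck2 (-1.43 ± 0.14). edgeR called 2371 genes higher and 2804 lower of 14771 tested, and 595 and 151 of these changed at least 2-fold. With library-size scaling the share of calls that were higher was 58.9% against 45.8% with TMM, for a median shift of 0.05 in log2 fold change.

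Of the p53 targets, 27 of 34 rose and 1 fell (28 and 1 adjusted over the list alone), among them Cdkn1a (1.13 ± 0.06), Trp53inp1 (1.33 ± 0.07) and Ccng1 (0.99 ± 0.06). The list stood above other genes by camera, a test of a gene list against the rest (median log2 fold change 0.70, adjusted p = 2.82e-15). Trp53 itself was -0.09 ± 0.06 (adjusted p = 0.256). DNA replication and E2F target genes went the other way: 45 of 49 fell and 0 rose (45 and 0 adjusted over the list alone), with Mcm6 of the replicative helicase at -0.84 ± 0.05, Uhrf1 at -1.18 ± 0.07 and Pola1 at -0.94 ± 0.06 (median log2 fold change -0.74, adjusted p = 7.47e-26). In the G2/M and mitosis list 47 of 49 fell and 0 rose (47 and 0 adjusted over the list alone), including Mki67 (-1.11 ± 0.07), Aurka (-0.78 ± 0.05) and Anln (-0.68 ± 0.04) (median log2 fold change -0.97, adjusted p = 8.05e-33). Replication-dependent histone genes did not follow the replication genes, since 14 of 35 rose and 0 fell (14 and 0 adjusted over the list alone) (median log2 fold change 0.87, adjusted p = 3.8e-05, and adjusted p = 0.241 with an estimated correlation). Those that rose included Hist1h1c (1.30 ± 0.09) and Hist1h2bc (1.15 ± 0.10), and histone genes have near-identical copies whose reads the counting could split. How fully the library kit captured histone transcripts was not tested, so their counts in any comparison may not follow total histone RNA. Immediate early genes, which growth and stress signals switch on, rose in 18 of 26 cases and fell in 0 (22 and 0 adjusted over the list alone), among them Dusp1 (1.80 ± 0.11) and Nr4a1 (1.38 ± 0.08) (median log2 fold change 0.46, adjusted p = 1.54e-10).

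Genes of secreted factors also moved. Of the inflammatory cytokines and chemokines, 16 of 33 rose and 1 fell (16 and 1 adjusted over the list alone) (median log2 fold change 0.70, adjusted p = 1.03e-05). They included Il11 (1.39 ± 0.11), Ccl7 (0.91 ± 0.10) and Il6, which went from 0.404 ± 0.257 to 1.83 ± 0.0994 CPM (2.18 ± 0.34, or 2.83 without replicate 3 of the day-0 group). Cxcl14 was 0.56 ± 0.30 (adjusted p = 0.163, and 1.45e-06 with the replicate number as a block). In the list of secreted proteases and their inhibitors 15 of 33 rose and 4 fell (15 and 5 adjusted over the list alone), with Plau (0.95 ± 0.08), which activates plasmin, and Mmp13 (1.80 ± 0.18) (median log2 fold change 0.41, adjusted p = 0.00076). Of the growth factors and IGF-binding proteins, 24 of 54 rose and 4 fell (25 and 5 adjusted over the list alone), and 33 and 10 with the replicate block (median log2 fold change 0.39, adjusted p = 0.000141). Ereg, an EGF-receptor ligand, rose by 1.91 ± 0.14 and Cyr61 by 0.94 ± 0.07. The complement list had 7 of 21 higher and 0 lower (8 and 0 adjusted over the list alone, 12 and 1 with the block, and 4 higher without replicate 2 of the day-2 group; median log2 fold change 0.32, adjusted p = 0.00737). Extracellular matrix genes went both ways: 18 of 63 fell and 10 rose (18 and 10 adjusted over the list alone), or 27 and 23 with the block. Their median was -0.02, which turned positive under library-size scaling, their mean was 0.01, and camera, with a downward sign, made no call (adjusted p = 0.533). Thbs1 (0.49 ± 0.05) and Dcn (1.41 ± 0.20) rose, and Fbn1 of the microfibrils was -0.38 ± 0.05.

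Lysosomal genes rose together at day 2, with 39 of 54 higher and 0 lower (42 and 0 adjusted over the list alone; median log2 fold change 0.29, adjusted p = 1.76e-13), among them the protease genes Ctsd (0.95 ± 0.05) and Ctsf (1.01 ± 0.07). Of the ribosomal protein genes, 64 of 80 fell and 1 rose (64 and 1 adjusted over the list alone) (median log2 fold change -0.21, adjusted p = 9.11e-14, and adjusted p = 0.241 with an estimated correlation), such as Rpl3 (-0.59 ± 0.06). In cholesterol biosynthesis 16 of 25 fell and 1 rose (18 and 1 adjusted over the list alone) (median log2 fold change -0.28, adjusted p = 8.08e-05, and adjusted p = 0.331 with an estimated correlation), such as Hmgcs1 (-0.44 ± 0.09). Interferon-stimulated genes had 3 of 47 higher and 2 lower (0 and 0 adjusted over the list alone; median log2 fold change 0.49, adjusted p = 0.0118, and adjusted p = 0.661 with an estimated correlation). Antigen presentation genes and natural killer cell ligands had 4 of 23 higher and 1 lower (4 and 1 adjusted over the list alone), with Tap1, of the peptide transporter, at 1.32 ± 0.15 (median log2 fold change 0.11, adjusted p = 0.19). Contractile genes had 3 of 26 higher and 1 lower (3 and 1 adjusted over the list alone; adjusted p = 0.379), and 15 and 7 with the block (adjusted p = 0.0261).

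Several markers of other cell types moved at day 2. Macrophage and blood cell markers had 4 of 20 higher and 0 lower (3 and 0 adjusted over the list alone, 8 and 0 with the block; median log2 fold change 0.31, adjusted p = 0.00692, and adjusted p = 0.427 with an estimated correlation). Their adjusted p was 0.0869 without replicate 2 of the day-0 group. Lyz2 rose by 1.04 ± 0.17, to 79.1 ± 6.83 CPM. Endothelial markers had 6 of 15 higher and 1 lower (6 and 1 adjusted over the list alone; median log2 fold change 0.67, adjusted p = 0.0175, and adjusted p = 0.0539 with an estimated correlation), with Esam at 2.34 ± 0.701 CPM. Epithelial markers had 5 of 15 higher and 1 lower (5 and 1 adjusted over the list alone; median log2 fold change 0.87, adjusted p = 0.00863, and adjusted p = 0.0648 with an estimated correlation), including Dsp (7.63 ± 1.05 CPM) and Perp, which is also a p53 target. Skeletal muscle markers had 6 of 18 higher and 0 lower (6 and 0 adjusted over the list alone; median log2 fold change 0.60, adjusted p = 0.00692, and adjusted p = 0.0695 with an estimated correlation). Neural markers had 2 of 15 higher and 0 lower (2 and 0 adjusted over the list alone; median log2 fold change 0.44, adjusted p = 0.183).

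**Figure D2:**
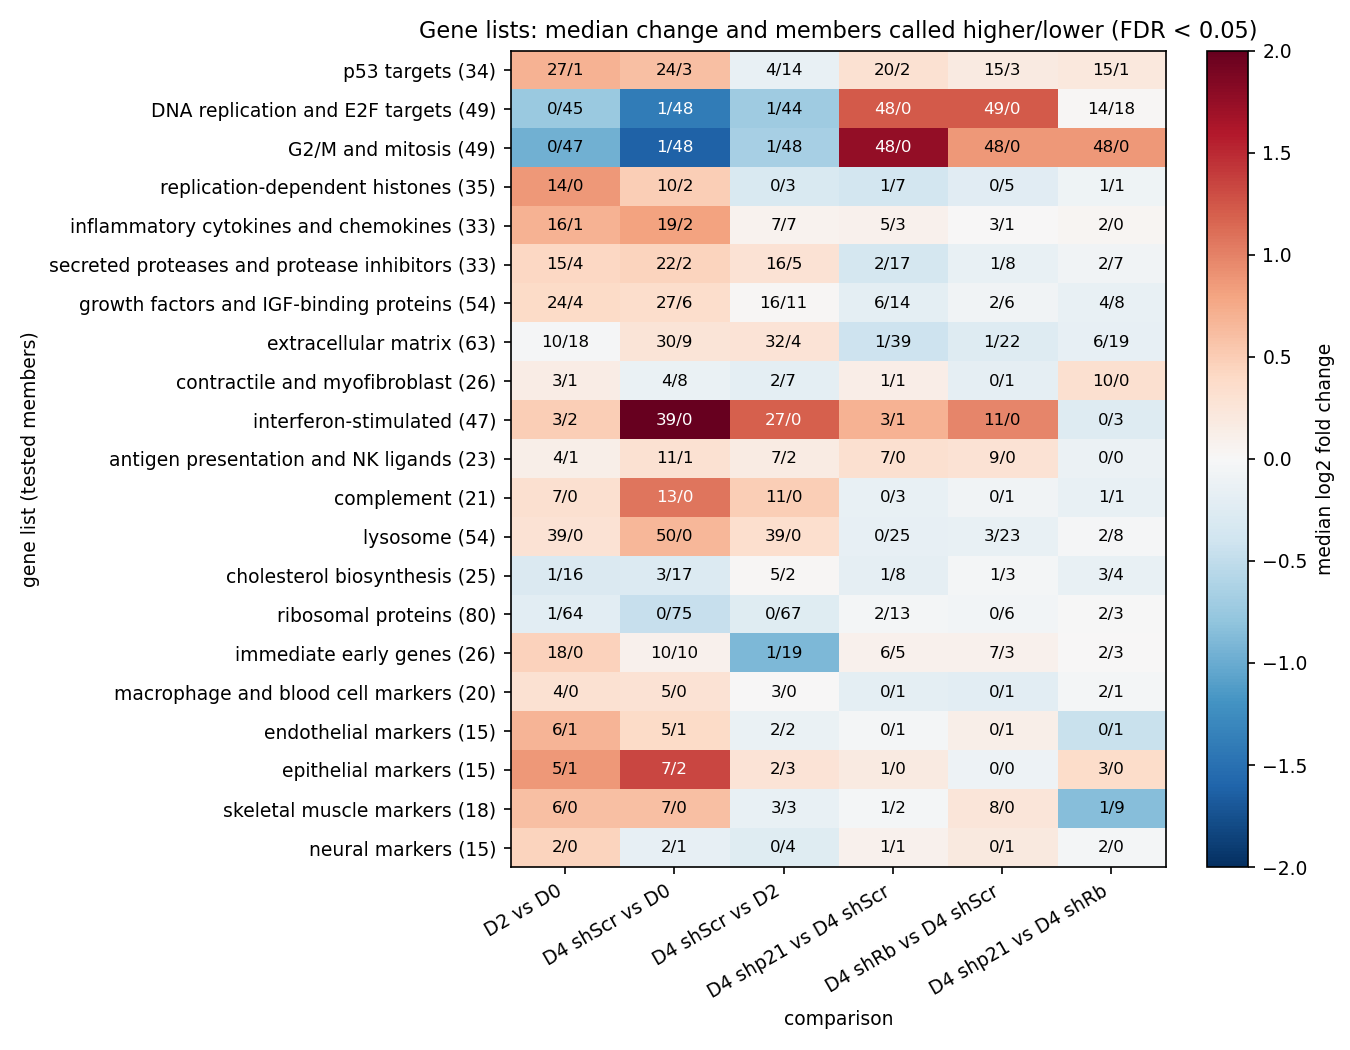
Heat map of the median log2 fold change of the 21 gene lists (vertical) in the 6 comparisons (horizontal), with the members called higher and lower in each field. The DNA replication and the G2/M lists were negative at day 2 (-0.74 and -0.97) and positive with shp21 (1.23 and 1.75) and shRb (1.23 and 0.87), and none of these 6 medians changed sign under library-size scaling.

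Irradiated cells with control virus at day 4 were compared with the proliferating cells, which differed from them by irradiation, virus and 4 days at once. The proteoglycan gene Dcn rose from 6.25 ± 1.46 to 74.5 ± 13.2 CPM (3.58 ± 0.19), Lum, another one, from 2.92 ± 1.55 to 50.6 ± 17.6 CPM (4.10 ± 0.55), and Pamr1 from 2.85 ± 0.803 to 36.7 ± 5.20 CPM. Tfrc, the receptor for transferrin-bound iron, was among the largest falls, from 205 ± 12.6 to 42.1 ± 4.29 CPM (-2.28 ± 0.09), with Mybl2 (-2.19 ± 0.10) and Mcm5 (-2.08 ± 0.09). Cdkn2a, which encodes p16 and ARF, rose from 35.5 ± 2.90 to 72.5 ± 5.27 CPM (1.03 ± 0.09), and Trp53 was -0.71 ± 0.06. edgeR called 4115 genes higher and 4182 lower, with 1392 and 482 changed at least 2-fold.

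In DNA replication 48 of 49 fell and 1 rose (48 and 1 adjusted over the list alone) and in G2/M and mitosis 48 of 49 fell and 1 rose (48 and 1 adjusted over the list alone). Their medians were -1.40 and -1.62 (adjusted p = 6.65e-25 and 7.15e-28, and adjusted p = 0.0685 with an estimated correlation for the G2/M list). Mcm6 was -1.72 ± 0.05 and Aurka -1.61 ± 0.05. Of the p53 targets 24 of 34 rose and 3 fell (25 and 3 adjusted over the list alone), including Psrc1 (0.99 ± 0.05) (median log2 fold change 0.60, adjusted p = 2.02e-06, and adjusted p = 0.0868 with an estimated correlation). Lysosomal genes were higher in 50 of 54 cases and lower in 0 (50 and 0 adjusted over the list alone; median log2 fold change 0.66, adjusted p = 1.02e-17), with Ctsf at 2.03 ± 0.07 and Naglu at 1.28 ± 0.06. Of the ribosomal protein genes 75 of 80 fell and 0 rose (75 and 1 adjusted over the list alone) (median log2 fold change -0.46, adjusted p = 1.21e-20, and adjusted p = 0.205 with an estimated correlation), among them Rps12 (-0.68 ± 0.04). Interferon-stimulated genes rose in 39 of 47 cases and fell in 0 (41 and 0 adjusted over the list alone; median log2 fold change 2.06, adjusted p = 4.68e-07, and adjusted p = 0.441 with an estimated correlation). Without replicate 3 of the shScr group they rose in 24 cases, with a median of 1.17. With all libraries Ifi27 of this list rose by 1.55 ± 0.21 and Eif2ak2, a kinase that senses double-stranded RNA, by 0.94 ± 0.17.

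Secreted factors at day 4 included Ccl7 (1.30 ± 0.10), Serpine2 (2.50 ± 0.14), Mmp19 (1.37 ± 0.09) and Igf1 (1.19 ± 0.12). In the inflammatory list 19 of 33 rose and 2 fell (19 and 2 adjusted over the list alone) (median log2 fold change 0.80, adjusted p = 0.00247, and adjusted p = 0.0868 with an estimated correlation). In proteases and inhibitors 22 of 33 rose and 2 fell (22 and 2 adjusted over the list alone) (median log2 fold change 0.45, adjusted p = 2.76e-05). In growth factors 27 of 54 rose and 6 fell (28 and 7 adjusted over the list alone) (median log2 fold change 0.36, adjusted p = 0.00316, and adjusted p = 0.104 with an estimated correlation). Complement genes rose in 13 of 21 cases and fell in 0 (14 and 0 adjusted over the list alone; median log2 fold change 1.07, adjusted p = 6.95e-05), with C1rl at 2.08 ± 0.18 and Cd55, which restrains complement, at 2.39 ± 0.25. Of the matrix genes 30 of 63 rose and 9 fell (31 and 9 adjusted over the list alone), or 44 and 14 with the block, such as Ogn (1.32 ± 0.11) (median log2 fold change 0.25, adjusted p = 0.0033, and adjusted p = 0.166 with an estimated correlation). Antigen presentation genes rose in 11 of 23 cases and fell in 1 (11 and 1 adjusted over the list alone; median log2 fold change 0.31, adjusted p = 0.0415, and adjusted p = 0.471 with an estimated correlation). Tap1 was at 1.89 ± 0.15 and Tap2 at 1.82 ± 0.14, and the call was lost without replicate 1 of the shScr group (adjusted p = 0.0506). Camera also called cholesterol biosynthesis lower (median log2 fold change -0.28, adjusted p = 0.0122, and adjusted p = 0.585 with an estimated correlation). It made no call for immediate early genes, of which 10 rose and 10 fell (10 and 10 adjusted over the list alone), with median 0.09, mean -0.12 and adjusted p = 0.709 in the downward direction. Skeletal muscle markers were not called (adjusted p = 0.0606) but were with the block (0.0434) and, unblocked, without replicate 1 or 3 of day 0 or replicate 1 of shScr (0.0493, 0.043 and 0.0433).

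Day 4 with control virus was also set against day 2, which asked what 2 further days and infection changed in irradiated cells; these were not separable. Genes induced by growth signals went down: Egr1 from 286 ± 44.4 to 58.8 ± 9.47 CPM (-2.29 ± 0.15), Egr2 (-2.55 ± 0.20), Ier2 (-1.70 ± 0.07) and Dusp5 (-1.79 ± 0.12). Matrix genes went up: Dcn (2.17 ± 0.17), Aspn (1.29 ± 0.11), Ogn (1.09 ± 0.11) and Col1a2, which encodes a chain of type I collagen (0.62 ± 0.06). Pamr1 (2.70 ± 0.19) and Ppp1r3c (3.39 ± 0.33) were among the largest rises. Cdkn2a rose from 31.8 ± 4.40 to 72.5 ± 5.27 CPM (1.18 ± 0.09), whereas Cdkn1a was 0.07 ± 0.06 (adjusted p = 0.358). edgeR called 2997 genes higher and 3411 lower, with 528 and 238 changed at least 2-fold.

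Of the immediate early genes 19 of 26 fell and 1 rose (19 and 1 adjusted over the list alone) (median log2 fold change -0.90, adjusted p = 3.6e-09). Of the matrix genes 32 of 63 rose and 4 fell (35 and 4 adjusted over the list alone) (median log2 fold change 0.27, adjusted p = 3.85e-06, and adjusted p = 0.0705 with an estimated correlation). Replication and mitosis genes fell further: 44 of 49 fell and 1 rose (45 and 1 adjusted over the list alone) and 48 of 49 fell and 1 rose (48 and 1 adjusted over the list alone). Their medians were -0.71 and -0.67 (adjusted p = 1.53e-19 and 1.29e-20, and adjusted p = 0.0705 and 0.0988 with an estimated correlation). Lysosomal genes rose in 39 of 54 cases and fell in 0 (41 and 0 adjusted over the list alone; median log2 fold change 0.33, adjusted p = 4.46e-13, and adjusted p = 0.0846 with an estimated correlation). Ribosomal protein genes fell in 67 of 80 and rose in 0 (69 and 0 adjusted over the list alone; median log2 fold change -0.24, adjusted p = 3.3e-15, and adjusted p = 0.395 with an estimated correlation). Proteases and inhibitors had 16 of 33 higher and 5 lower (16 and 6 adjusted over the list alone; median log2 fold change 0.29, adjusted p = 0.0126, and adjusted p = 0.0915 with an estimated correlation), with Adamts5 at 1.71 ± 0.11 and Plau at -0.81 ± 0.08. Complement had 11 of 21 higher and 0 lower (11 and 0 adjusted over the list alone; median log2 fold change 0.49, adjusted p = 0.000666). Of the p53 targets 14 of 34 fell and 4 rose (14 and 4 adjusted over the list alone), with Mdm2 at -0.71 ± 0.09; camera made no call (adjusted p = 0.0652) but did with the block (0.0393). Contractile genes were not called either (adjusted p = 0.152) but were with the block (0.00127) and, unblocked, without replicate 2 of the day-2 group (0.0264) or replicate 3 of the shScr group (0.0432).

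Interferon-stimulated genes rose in the comparison of day 4 with day 2, by an amount that depended on 1 library. Of 47, 27 rose and 0 fell (31 and 0 adjusted over the list alone; median log2 fold change 1.20, adjusted p = 8.52e-07, and adjusted p = 0.641 with an estimated correlation). Without replicate 3 of the shScr group 8 rose, the median was 0.66 and camera still made the call (adjusted p = 2e-04), whereas 32 and 29 rose without replicate 1 or 2. The mean of the list, as log2(CPM + 1), was 3.59 in that library and 2.46 and 2.72 in the other shScr libraries. It ran from 2.07 to 2.15 at day 2 and from 1.84 to 1.86 at day 0, and in the other day-4 groups from 3.27 to 3.84 with shp21 and from 3.29 to 4.46 with shRb. Stat2 (1.78 ± 0.32) and Ifi27 (1.03 ± 0.21) were among the genes that rose. The ribosomal RNA gene Rn45s held 1.88% of the counts of shScr replicate 3, against 0.549% and 0.395% in the other shScr libraries. It held 3.81% in shRb replicate 3, where the mean of the interferon list was 3.38.

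Libraries with the hairpin against p21 were compared with shScr at day 4 to ask which genes depend on p21 in irradiated cells. Genes of mitosis and DNA replication rose, and genes of the extracellular matrix and of several secreted proteases fell. Anln, which encodes the cytokinesis protein anillin, rose from 76.4 ± 1.14 to 287 ± 5.58 CPM (1.91 ± 0.04, adjusted p = 5.62e-13), and Mki67, the proliferation marker, from 76.2 ± 5.76 to 228 ± 10.8 CPM (1.58 ± 0.07). The largest rises included Polq (2.32 ± 0.16), Kif18b (2.22 ± 0.12) and Dlgap5 (2.19 ± 0.07). After Cdkn1a, the largest falls included Cemip (-1.31 ± 0.19), Sema3b (-1.29 ± 0.18) and the calcium channel gene Cacna1g (-1.17 ± 0.11). Lmnb1 rose from 27.2 ± 1.15 to 61.3 ± 2.36 CPM (1.17 ± 0.06). edgeR called 2454 genes higher and 2158 lower, with 398 and 99 changed at least 2-fold. Under library-size scaling the genes called lower numbered 1264 and the share of calls that were higher was 73.4% against 53.2%, for a median shift of 0.08.

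Of the G2/M and mitosis genes 48 of 49 rose and 0 fell (48 and 0 adjusted over the list alone), and of the DNA replication genes 48 of 49 rose and 0 fell (48 and 0 adjusted over the list alone). Their medians were 1.75 and 1.23 (adjusted p = 6.94e-54 and 2.54e-43). Besides Anln, examples were Aurka (1.80 ± 0.05), the motor gene Cenpe (2.04 ± 0.06), Rrm2 of nucleotide synthesis (1.88 ± 0.08) and Clspn (1.95 ± 0.08). Of the p53 targets 20 of 34 rose and 2 fell (21 and 2 adjusted over the list alone) although Cdkn1a is on the list (median log2 fold change 0.30, adjusted p = 2.64e-05, and adjusted p = 0.178 with an estimated correlation). Mdm2 rose to 381 ± 38.3 CPM (0.84 ± 0.09), Ei24 by 0.76 ± 0.05 and Eda2r by 0.77 ± 0.07. Of the matrix genes 39 of 63 fell and 1 rose (40 and 1 adjusted over the list alone), with Col1a1 at -0.84 ± 0.07, Col1a2 at -0.70 ± 0.06 and the laminin gene Lamc1 at -0.81 ± 0.06 (median log2 fold change -0.42, adjusted p = 3.17e-12). In proteases and inhibitors 17 of 33 fell and 2 rose (18 and 2 adjusted over the list alone) (median log2 fold change -0.35, adjusted p = 0.000302). Adamts5, an aggrecan-cleaving protease, was -1.14 ± 0.10 and Adamts1 -0.97 ± 0.08, whereas Plau rose by 1.29 ± 0.08.

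Cytokine and growth factor genes went both ways with shp21. Icam1 (0.90 ± 0.11), Lif (0.77 ± 0.13) and Ereg (1.20 ± 0.13) rose, and Nov (-0.91 ± 0.08) and Igfbp6 (-0.67 ± 0.08) fell. Cxcl14 was -0.69 ± 0.29 (adjusted p = 0.0809, and 1.42e-08 with the replicate block), Il6 0.63 ± 0.27 (0.0919, and 0.0303 with the block) and Cdkn2a -0.17 ± 0.09 (0.147, and 0.0335 with the block). The inflammatory list had 5 of 33 higher and 3 lower (4 and 3 adjusted over the list alone, 10 and 6 with the block; adjusted p = 0.646), with 3 higher without replicate 3 of the shp21 group. Under library-size scaling 7 of the inflammatory genes were higher and 0 lower. Of the growth factors 14 of 54 fell and 6 rose (15 and 6 adjusted over the list alone), or 30 and 7 with the block (median log2 fold change -0.20, adjusted p = 0.0226, and adjusted p = 0.24 with an estimated correlation). Without replicate 1 of shScr that call was lost (adjusted p = 0.0643) and 9 fell, as they did without replicate 1 of shp21, while 7 fell and 3 rose without replicate 3 of shp21. Interferon-stimulated genes had 3 of 47 higher and 1 lower (1 and 1 adjusted over the list alone, 15 and 1 with the block; median log2 fold change 0.70, adjusted p = 0.000607, and adjusted p = 0.708 with an estimated correlation), and 31 were higher without replicate 3 of the shScr group. Their median was 1.32 without that library and 0.43 without replicate 1 of shScr. Antigen presentation genes had 7 of 23 higher and 0 lower (7 and 0 adjusted over the list alone; median log2 fold change 0.33, adjusted p = 0.0124, and adjusted p = 0.563 with an estimated correlation), but without replicate 1 of shp21 adjusted p was 0.0634. Ulbp1, a ligand of the natural killer receptor NKG2D, rose by 0.92 ± 0.13 and Tap1 by 0.63 ± 0.13.

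Lysosomal genes were lower with shp21 in 25 of 54 cases and higher in 0 (26 and 0 adjusted over the list alone; median log2 fold change -0.17, adjusted p = 2.32e-06, and adjusted p = 0.24 with an estimated correlation), such as Gaa (-0.46 ± 0.05) and Arsa (-0.61 ± 0.07). Under library-size scaling 15 lysosomal genes were lower and 2 higher. In cholesterol biosynthesis 8 of 25 fell and 1 rose (8 and 1 adjusted over the list alone), or 14 and 1 with the block, such as Mvd (-0.71 ± 0.10) (median log2 fold change -0.17, adjusted p = 0.0106, and adjusted p = 0.708 with an estimated correlation). Camera placed the ribosomal protein genes lower (median log2 fold change -0.04, adjusted p = 0.0124, and adjusted p = 0.749 with an estimated correlation; the median turned positive under library-size scaling, which moves all genes alike). Without replicate 1 of shScr or replicate 3 of shp21 the call was lost (adjusted p = 0.136 and 0.129). Contractile and complement genes were not called (adjusted p = 0.365 and 0.0855) but both were with the block (0.0178 and 0.0178), and contractile genes also without replicate 2 of shp21 (0.0268). Histone genes, of which 7 of 35 fell and 1 rose (6 and 1 adjusted over the list alone), were not called (adjusted p = 0.0792) except without replicate 2 of shScr (0.0399) or replicate 3 of shp21 (0.016). Hist1h1c and Hist1h2bc fell with shp21 (-0.67 ± 0.09 and -0.69 ± 0.09).

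The hairpin against Rb was compared with shScr at day 4 to ask which genes depend on Rb in irradiated cells. DNA replication genes rose. Prim1, a subunit of primase, rose from 5.83 ± 0.420 to 22.9 ± 1.24 CPM (1.97 ± 0.07, adjusted p = 1.51e-10), Mcm3 from 26.5 ± 2.16 to 91.5 ± 7.31 CPM (1.79 ± 0.07) and Ccne2, which encodes cyclin E2, from 4.79 ± 0.364 to 17.6 ± 0.694 CPM (1.87 ± 0.12). Cdt1 (1.78 ± 0.09) and Chaf1b (1.70 ± 0.10) were also among the largest rises. After Rb1, the largest falls included Tmem123 (-1.07 ± 0.06), Cmtm6 (-1.03 ± 0.08), Ogn (-0.94 ± 0.10) and Thbs1 (-0.92 ± 0.05), which encodes the matrix protein thrombospondin. edgeR called 1689 genes higher and 1509 lower, with 269 and 14 changed at least 2-fold, and with the replicate block 2505 were lower. The genes called higher include muscle and liver transcripts described below, such as Myh4, Alb and Atp2a1, which were not left out of the counts. Without replicate 2 or 3 of the shRb group 995 and 968 were lower. Under library-size scaling 2866 were higher and 612 lower, so that 82.4% of calls were higher against 52.8%, for a median shift of 0.10.

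Of the DNA replication genes 49 of 49 rose and 0 fell (49 and 0 adjusted over the list alone) and of the G2/M and mitosis genes 48 of 49 rose and 0 fell (48 and 0 adjusted over the list alone). Their medians were 1.23 and 0.87 (adjusted p = 4.73e-56 and 2.47e-45). Mcm6 (1.69 ± 0.05) and Pola1 (1.57 ± 0.06) rose, as did Aurka (0.98 ± 0.05), Mki67 (0.76 ± 0.07) and Lmnb1 (0.84 ± 0.06). Of the p53 targets 15 of 34 rose and 3 fell (16 and 3 adjusted over the list alone), including Ei24 (0.43 ± 0.05) and Btg2 (0.52 ± 0.08) (median log2 fold change 0.18, adjusted p = 0.00423, and adjusted p = 0.366 with an estimated correlation). Of the matrix genes 22 of 63 fell and 1 rose (27 and 1 adjusted over the list alone), or 47 and 2 with the block, such as Col5a2 (-0.44 ± 0.05) and Col12a1 (-0.38 ± 0.05) (median log2 fold change -0.26, adjusted p = 8.86e-09). In proteases and inhibitors 8 of 33 fell and 1 rose (9 and 1 adjusted over the list alone), or 18 and 2 with the block (median log2 fold change -0.15, adjusted p = 0.00571, and adjusted p = 0.0813 with an estimated correlation), with Timp3 at -0.50 ± 0.10 and Plau at 0.44 ± 0.08. Icam1 rose by 0.78 ± 0.11, and Vcam1, another adhesion molecule, was -0.72 ± 0.07. The inflammatory list as a whole had 3 of 33 higher and 1 lower (2 and 1 adjusted over the list alone, 7 and 4 with the block; adjusted p = 0.859). Cxcl14 was -0.23 ± 0.28 (adjusted p = 0.629, and 0.0085 with the block).

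Several lists depended on single libraries with shRb. Interferon-stimulated genes had 11 of 47 higher and 0 lower (27 and 0 adjusted over the list alone, 30 and 0 with the block; median log2 fold change 0.98, adjusted p = 3.05e-07, and adjusted p = 0.597 with an estimated correlation). The number higher was 2, 4 and 36 without replicates 1, 2 and 3 of shScr and 3, 24 and 19 without those of shRb. The median was 1.63 without replicate 3 of shScr and 0.35 without replicate 1 of shRb. Antigen presentation genes had 9 of 23 higher and 0 lower (9 and 0 adjusted over the list alone; median log2 fold change 0.28, adjusted p = 0.000815, and adjusted p = 0.366 with an estimated correlation). That was 5 higher without replicate 1 or 2 of shScr or replicate 1 of shRb, the last with adjusted p = 0.0626, and Ulbp1 rose by 1.24 ± 0.13 and H2-Q4 by 1.28 ± 0.18. Lysosomal genes had 23 of 54 lower and 3 higher (31 and 4 adjusted over the list alone; median log2 fold change -0.15, adjusted p = 1.47e-05, and adjusted p = 0.366 with an estimated correlation), with Idua at -0.90 ± 0.07 and Npc1 at -0.59 ± 0.06. The number lower was 13, 15, 11 and 12 without shScr replicate 1 or 2 or shRb replicate 2 or 3. Under library-size scaling 7 lysosomal genes were lower and 6 higher.

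Camera placed contractile genes lower with shRb (median log2 fold change -0.19, adjusted p = 0.00423, and adjusted p = 0.693 with an estimated correlation), but not without replicate 3 of shScr (0.0583) or replicate 2 of shRb (0.137). Of these 1 of 26 fell (1 adjusted over the list alone, 20 with the block, and 7 without replicate 2 of shScr). Ribosomal protein genes were also placed lower (median log2 fold change -0.05, adjusted p = 0.00547, and adjusted p = 0.757 with an estimated correlation; the median turned positive under library-size scaling, which does not bear on camera). The call was lost without replicate 1 of shScr (0.131) or replicate 3 of shRb (0.688). Histone genes were placed lower as well (median log2 fold change -0.22, adjusted p = 0.0397, and adjusted p = 0.693 with an estimated correlation), which was lost with the block (0.0568) and without shScr replicate 3 (0.146), shRb replicate 1 (0.179) or shRb replicate 2 (0.137). Hist1h1c fell by 0.98 ± 0.09 on the log2 scale. Complement, growth factor and cholesterol genes were not called (adjusted p = 0.599, 0.257 and 0.284), except cholesterol genes without replicate 1 of shRb (0.0313), and their negative medians turned positive under library-size scaling.

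Transcripts of other tissues were found in the shRb libraries. Myh4, a myosin heavy chain gene of fast muscle on chromosome 11 at 67238029 to 67260446, was at 21.3 ± 3.56 CPM with shRb and had 0 counts in the shScr libraries, so it was at least 693-fold higher (floor of 3 counts over the group). Alb, the serum albumin gene on chromosome 5 at 90460897 to 90476602, was at 16.2 ± 2.40 CPM with shRb and 0.0379 ± 0.0329 with shScr, where it had 4 counts. Atp2a1, the calcium pump of fast muscle, was at 16.3 ± 2.98 against 0.324 ± 0.0803 CPM. Of the skeletal muscle markers 8 of 18 rose and 0 fell (9 and 0 adjusted over the list alone), with mean 2.16 and median log2 fold change 0.24, adjusted p = 0.000458, and adjusted p = 0.0541 with an estimated correlation. Among genes with a mean of at least 5 CPM over the compared libraries, Myh4, Alb and Atp2a1 were the 3 largest rises with shRb, in the same libraries in which the replication genes rose.

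**Figure D3:**
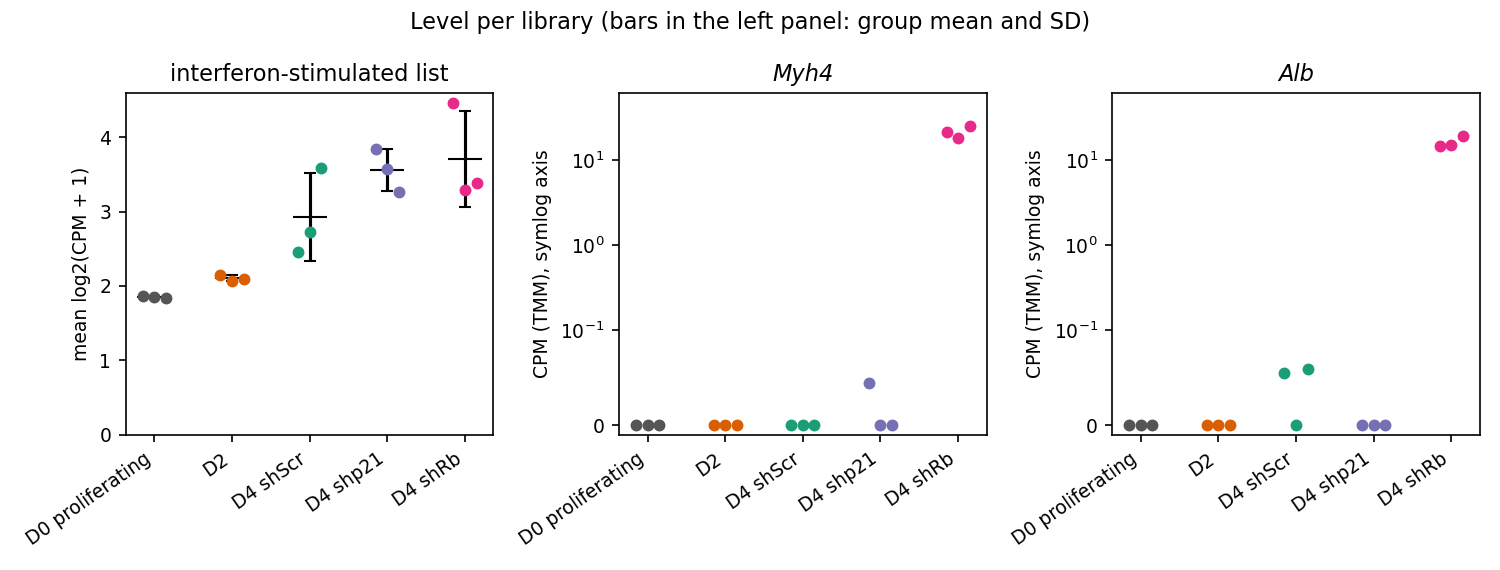
For each of the 15 libraries, the mean log2(CPM + 1) of the interferon-stimulated list, with bars for the group mean and SD, and the CPM of Myh4 and Alb on an axis that is linear near 0 and logarithmic above. Replicate 3 of the shScr group lay at 3.59 on the interferon scale against 2.46 and 2.72 in the other shScr libraries, and Myh4 averaged 21.3 CPM in the shRb group.

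The knockdowns were compared directly, which tested whether their effects differed without shScr as the reference. The shScr libraries still entered the filter, the scaling and the shared estimate of the spread. Mitosis genes were higher with shp21 than with shRb. Anln was at 287 ± 5.58 against 124 ± 4.83 CPM (1.21 ± 0.04, adjusted p = 1.41e-10), Cenpe at 109 ± 9.10 against 51.2 ± 2.85 CPM (1.09 ± 0.06) and Mki67 differed by 0.82 ± 0.07. Cxcl14 was -0.46 ± 0.28 (adjusted p = 0.299, and 4.26e-06 with the replicate block). Tmem123 (1.52 ± 0.06), the transcription factor gene Mybl1 (1.46 ± 0.08), Cmtm6 (1.42 ± 0.08) and H2afx, which encodes a histone phosphorylated at DNA breaks (1.41 ± 0.05), were among those furthest above. Leaving out the targets and the tissue transcripts, Ptx3 (-1.41 ± 0.26), Arpc5 (-1.03 ± 0.08) and Adamts5 (-1.02 ± 0.10) were among those furthest below. edgeR called 1655 genes higher with shp21 and 1265 lower, with 72 and 126 at least 2-fold apart. With the replicate block these were 2490 and 2162, and without replicate 3 of shp21 837 were lower. The genes called lower include muscle and liver transcripts of the shRb libraries, such as Tnnt3 and Hp, which were not left out of the counts.

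Of the G2/M genes 48 of 49 were higher with shp21 and 0 lower (48 and 0 adjusted over the list alone; median log2 fold change 0.86, adjusted p = 4.37e-46). DNA replication genes divided, with 14 of 49 higher and 18 lower (17 and 18 adjusted over the list alone). Their median was 0.02, which turned negative under library-size scaling, their mean 0.04, and camera, with a downward sign, made no call (adjusted p = 0.747). Ccna2 (0.90 ± 0.08) and Clspn (0.62 ± 0.07) were higher with shp21, and Mcm6 (-0.50 ± 0.05) and Ccne1 (-0.77 ± 0.07) lower. Of the p53 targets 15 of 34 were higher and 1, Cdkn1a, lower (17 and 2 adjusted over the list alone; median log2 fold change 0.21, adjusted p = 0.000884, and adjusted p = 0.343 with an estimated correlation), such as Apaf1 (0.54 ± 0.04). Matrix genes were lower in 19 of 63 cases and higher in 6 (21 and 6 adjusted over the list alone, 34 and 10 with the block; median log2 fold change -0.16, adjusted p = 0.00651, and adjusted p = 0.343 with an estimated correlation), with Lamc1 at -0.66 ± 0.06 and Thbs1 at 0.49 ± 0.05. The number lower was 9 without replicate 3 of shp21 and 11 without replicate 1 of shRb. Contractile genes were higher in 10 of 26 cases and lower in 0 (17 and 0 adjusted over the list alone, 19 and 0 with the block; median log2 fold change 0.33, adjusted p = 0.00031, and adjusted p = 0.722 with an estimated correlation), such as Tpm4 (0.68 ± 0.08). That number was 6, 16 and 5 without replicates 1, 2 and 3 of shp21 and 5 without replicate 2 of shRb.

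Muscle markers were lower with shp21 than with shRb in 9 of 18 cases and higher in 1 (9 and 2 adjusted over the list alone; median log2 fold change -0.86, adjusted p = 6.88e-06). The muscle transcripts of the shRb libraries described above enter this comparison. Against shScr the median of the list was 0.24 with shRb and -0.04 with shp21, the latter positive under library-size scaling. Camera made no call for proteases, growth factors, complement or cholesterol genes (adjusted p = 0.108, 0.243, 0.243 and 0.0852). With the block it called each of them (0.0376, 0.0184, 0.0367 and 0.0095), all lower with shp21. Cholesterol genes were also called without replicate 1 of shp21 (0.0406) or replicate 3 of shRb (0.00672). Interferon-stimulated genes were not called (adjusted p = 0.243) except without replicate 1 of shp21 (0.048), replicate 2 of shRb (0.0208) or replicate 3 of shRb (0.0485). Ribosomal protein genes were not called (adjusted p = 0.747) except without replicate 3 of shRb (0.0153).

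The knockdowns shared many calls against shScr: 1180 genes were higher in both and 820 lower in both, where independent lists of the same sizes would share 280.6 and 220.5. Another 124 went in opposite directions, against 497.5 for independent lists. In 20 simulated draws of unchanged groups that shared simulated shScr libraries, edgeR called 0 genes in the same direction. In the draws 141 to 192 genes passed an unadjusted p of 0.05 in both comparisons with the same sign, against 3083 in the data. Each library was drawn on its own, without pairing by replicate number and without a shift of the whole shScr group. Over genes, which are not independent replicates, the covariance of the fold changes was 0.114 against 0.0344 to 0.0404 in the draws, a difference of 0.0763 from their mean. Pearson's r was 0.423 against 0.521 to 0.578, and 72.3% of genes had the same sign against 66.6% to 68.4%. The 3 shScr libraries could not be split, so part of the excess may come from the shared controls. With the replicate block 3091 genes were called in the same direction in place of 2000.

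**Figure D4:**
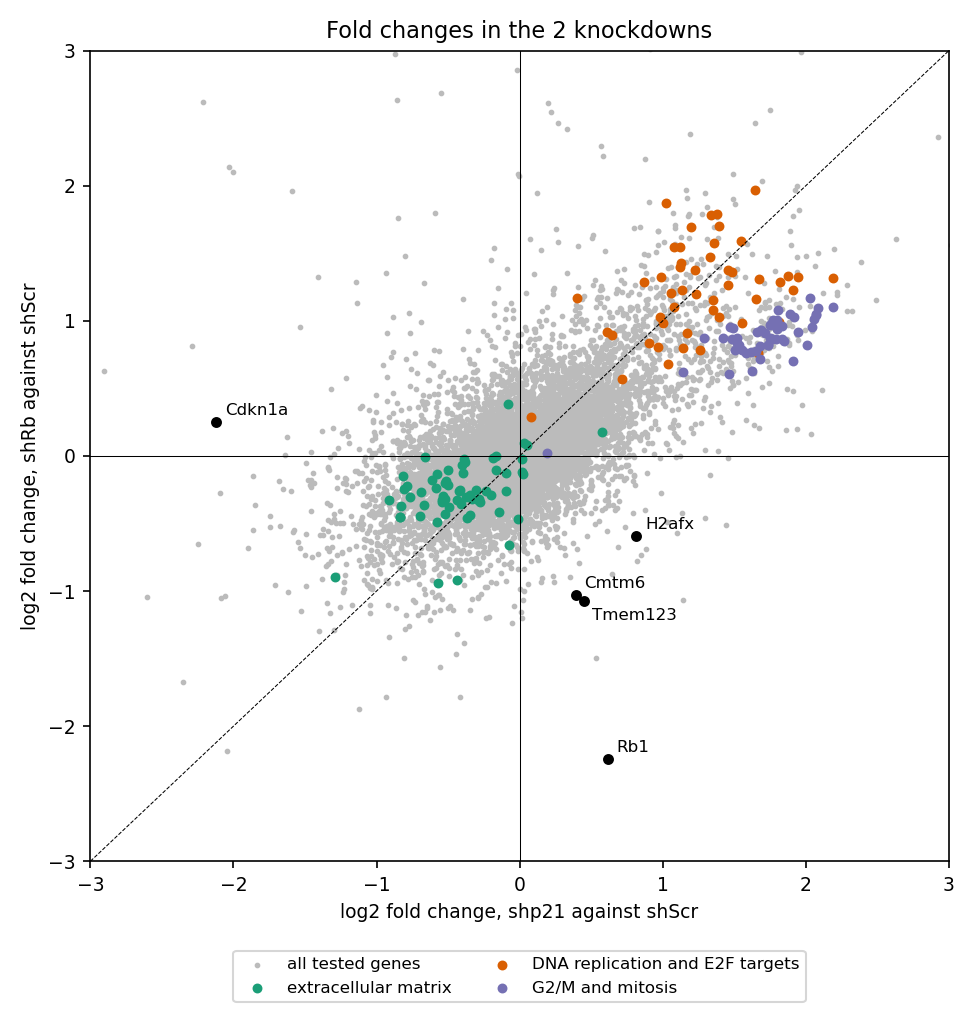
Each point is a gene, with its log2 fold change against shScr for shp21 (horizontal) and shRb (vertical), coloured for the matrix, replication and G2/M lists; the dashed line marks equal change, and 70 genes lie outside the axes at 3. G2/M genes had a median of 1.75 with shp21 and 0.87 with shRb, and replication genes 1.23 and 1.23.

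Genes called at day 2 against day 0 were followed into the knockdowns. The day-4 libraries entered the choice of these genes only through the filter, the scaling and the shared estimate of the spread. Of the 2804 that were lower at day 2, 1091 were higher with shp21 against 465.8 for independent lists, and 868 were higher with shRb against 320.6. Another 415 were lower with shp21 against 409.7 and 255 with shRb against 286.5, and the medians of the set were 0.09 with shp21 and 0.07 with shRb. Over all 14771 genes Pearson's r between the day-2 change and the knockdown change was -0.0544 for shp21 and 0.0241 for shRb, and Spearman's rho was -0.105 and -0.114. Anln (-0.68 ± 0.04 at day 2) and Mcm6 (-0.84 ± 0.05) were among them. By camera the set stood above other genes with shp21 (adjusted p = 1.67e-08) and with shRb (adjusted p = 4.86e-09). It stood higher with shp21 than with shRb before adjustment over the sets (0.0482) but not after it (adjusted p = 0.0965). The unadjusted value was 0.349 with an estimated correlation and 0.0937 with the replicate block. Of the 2371 genes that were higher at day 2, 492 were lower with shp21 against 346.4 for independent lists (adjusted p = 0.113). With shRb 385 were lower against 242.2 (adjusted p = 0.0214, but p = 0.247 with an estimated correlation).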

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

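Written after the result was seen were the tests of adult muscle, of muscle differentiation, of immune cells, of the virus, of depth and of reversal, and the tests of a single library for the rise of interferon genes in shScr and at day 4, which were separated from that of the calls in shScr against day 2 once the latter was known. The other tests here were written before their result was seen, although Alb and Hp were known by then and were left out of the liver list.

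In all, 124 genes were called in opposite directions by shp21 and shRb against shScr, and the direct difference was called by edgeR for each, which the choice of these genes all but fixed. They include muscle and liver transcripts of the shRb libraries, such as Tnnt3 and Hp. Besides Cdkn1a and Rb1 and with a mean of at least 5 CPM, the largest differences (shp21 minus shRb, log2) were those of Tmem123 (1.52), Cmtm6 (1.42) and H2afx (1.41). Each of these 3 was higher with shp21 and lower with shRb than with shScr. Whether this came from the loss of the targets or from off-target effects of a hairpin was not tested.

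Muscle and liver transcripts stood out in the shRb libraries, with Myh4 at 21.3 ± 3.56 CPM, Alb at 16.2 ± 2.4 and Atp2a1 at 16.3 ± 2.98. Muscle differentiation of the fibroblasts was the biological explanation that was tested. Of 28 abundant liver genes 24 were above the shScr and shp21 libraries in every shRb library, which argues against it as the whole cause. Whether it had a part in the muscle transcripts cannot be told. Of 6 detected myogenic regulators and developmental myosins 1 was above in the same way, but all 6 lay near the floor (0.0125 to 0.121 CPM with shRb). RNA or reads from adult tissues may be a source, since 24 of 28 abundant liver genes and 19 of 26 abundant adult muscle genes were above in that way, where chance gives 0.333 and 0.31 genes. Of these lists 4 liver and 5 muscle genes exceeded 1 CPM in shScr, and the muscle list summed to 287 CPM against 241. Whether RNA was mixed before library preparation or reads were assigned to the wrong library was not tested.

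Changes shared by the knockdowns were the second pattern, with 2000 genes called in the same direction. Shared shScr libraries as the whole cause, through random spread between libraries, are argued against by a covariance of 0.114. That is over 2 times the highest of 0.0404 in simulated unchanged groups. A shift of the whole shScr group was not simulated, so the draws cannot decide on it. A difference in depth as the whole cause is argued against too, since 1888 genes were called in the same direction with counts thinned to 1 depth. A reversal of the day-2 change may account for part of it: 61.4% of the genes higher in both knockdowns (724 of 1180) were lower at day 2, against 19.0% of all tested genes. Whether it accounts for the genes lower in both cannot be told, since 27.4% (225 of 820) were higher at day 2 against 16.1% of all tested genes, and over all genes Pearson's r with the day-2 change was -0.0544 for shp21 and 0.0241 for shRb (Spearman's rho -0.105 and -0.114).

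Interferon-stimulated genes at day 4 were the third pattern. In shScr against day 2 a single library could account for many calls and part of the size: without replicate 3 of shScr 8 of 47 genes were called, as the median fell from 1.20 to 0.66 and the median SE went from 0.49 to 0.43. A single library as the cause of the rise itself is argued against by 31 of 47 genes with shScr replicates 1 and 2 above every day-2 library (chance gives 10%), and by 28 of 47 with all 9 day-4 libraries above every day-0 and day-2 library (chance gives 0.02%). Whether immune cells made up a larger share cannot be told: 0 of 20 tested markers behaved so, but edgeR called 5 of the 20, including Lyz2, higher in shScr against day 0, and markers present at day 0 would hide a small share. Whether the virus or the later day raised these genes cannot be told apart with the same 28 of 47, because every day-4 library was infected.

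Other splits of the 6 libraries of each comparison were fitted alone, 10 per comparison; 3 against 3 libraries are too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many calls. The real split gave 4918 calls for day 2 against day 0, 7784 and 5898 for shScr against day 0 and day 2, 4157 for shp21, 2332 for shRb and 2219 for shp21 against shRb. The highest of the other splits gave 0 in each comparison by edgeR. At an unadjusted p under 0.05 the real splits gave 6186, 8460, 7045, 5886, 4378 and 4355 genes and the highest others 517, 276, 498, 704, 968 and 1109. In the same order, the 3 other splits that parted all same-numbered libraries gave at most 83, 48, 143, 137, 94 and 102. The 6 splits that kept some together included the highest others.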

How the results depend on the processing

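Library-size scaling, leaving out replicate 2 of every group, leaving out Rn45s, thinning and list tests without single libraries were tests chosen after seeing the data; the other alternatives were planned. No gene or list test was called in opposite directions by the fits compared. Under library-size scaling 1264 genes were lower with shp21 (2158 with TMM), and 2866 were higher and 612 lower with shRb (1689 and 1509). With the replicate number as a block 2505 genes were lower with shRb, 2490 were higher and 2162 lower with shp21 against shRb, and 3091 in place of 2000 were called in the same direction by both knockdowns. The block raised the lists called in shp21 against shRb from 5 to 9. In that comparison it took the camera value of the genes lower at day 2 from 0.0482 to 0.0937, unadjusted. Besides the calls printed with their blocked value in the report, the block changed no other call of a named gene or list. Leaving out single libraries gave 968 to 1484 genes lower with shRb and 837 to 1288 lower in shp21 against shRb. The shRb comparison had 995 and 968 without replicates 2 and 3 of shRb, and the other had 837 without replicate 3 of shp21; other counts stayed within 1.5 times. With an estimated correlation the lists called went from 17 to 9 for day 2 against day 0, 13 to 4 and 9 to 2 for shScr against day 0 and day 2, 11 to 4 for shp21, 12 to 3 for shRb and 5 to 2 for shp21 against shRb. The unadjusted camera value went from 0.0214 to 0.247 for the genes higher at day 2 with shRb, and for those lower at day 2 from 0.0482 to 0.349 in shp21 against shRb. For all of these the cause was not tested. Of 589 gene results, 574 were called and 506 of these under every alternative that tested the gene (578 results under the stricter filter, 587 in fits of the compared groups and 588 with DESeq2). Leaving out any 1 library lost 59, leaving out replicate 2 of every group 34, fitting only the compared groups 21, library-size scaling 12, thinning 9, no filter 4, DESeq2 2 and a stricter filter 1, while RLE factors and leaving out Rn45s lost 0. Of 126 list results, fry lost 9 calls and gained 13, leaving out replicate 2 of every group lost 2 and gained 4, and RLE factors changed 0. Library-size scaling, which moves all genes alike, turned the sign of the medians of 10 lists, each closer to 0 than its shift: matrix genes at day 2; ribosomal, endothelial and muscle genes with shp21; growth factor, complement, cholesterol and ribosomal genes with shRb; and replication and immediate early genes in shp21 against shRb (the last also with RLE factors). Depth limits genes near the floor of 0.0484 to 0.111 CPM. Where both compared groups lay near it, small differences could not be judged.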

Other observations

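The test of ATF4 targets was written after the falls of amino acid genes at day 2 had been seen. Some genes with large falls at day 2 make or import amino acids, and no list of such genes alone was tested. Besides Slc7a5 and Pck2, these included Slc7a11 (-1.38 ± 0.15), the cystine transporter, and Cth (-1.41 ± 0.15), which makes cysteine. Stc2 (-1.56 ± 0.19) and Trib3 (-1.60 ± 0.23), which ATF4 is known to induce, were lower too. Of 31 further ATF4 targets, listed without these genes, edgeR called 30 lower (median -0.67, camera p = 5.49e-19, and p = 0.0476 with an estimated correlation). Examples outside the naming rule, chosen after their values were seen, were Psat1 (-1.22 ± 0.09) of serine synthesis, Shmt2 (-1.15 ± 0.08) and the asparagine synthetase gene Asns (-1.03 ± 0.13). Atf4 itself was -0.60 ± 0.07.

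Lower activity of the transcription factor ATF4 at day 2 stays a hypothesis, with 30 of 31 targets called lower. The list was written after falls of amino acid genes had been seen in the same libraries, so the test was not independent of them. Several members of the list, such as Psat1 and Asns, are amino acid genes too. The test therefore cannot tell lower ATF4 activity apart from a fall of amino acid genes for another reason. Medium and cell density are not described per group, so a difference in amino acid supply could give the same values. In shScr against day 0, 28 of the 31 were lower and 1, Ddit3 (0.88 ± 0.15, also outside the naming rule), was higher (median -0.71, p = 3.59e-10, and p = 0.143 with an estimated correlation). Against day 2, 7 were higher and 8 lower (p = 0.952 at the preset correlation). With shp21 17 were lower (p = 6e-08, and p = 0.2 with an estimated correlation) and with shRb 14 (p = 1.73e-07, and p = 0.215). In shp21 against shRb 2 were lower (p = 0.135 at the preset correlation).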
